A study of Homo sapiens with 2 samples.

How the data were processed

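Total RNA of AGS cells stably transfected with a control or a GGT7 plasmid was sequenced on standard Illumina libraries made from 1 ug of RNA, per the labels' protocols. There were 2 libraries, 1 per group, both at 2 weeks, and the groups were taken from the sample labels. The submitters' processing notes name HISAT2, StringTie 1.3.0, edgeR and the build GRCh38, with no roles. The annotation, the counting tool and its strand setting are not given in the sources used here.

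The deposited table gives a count and an FPKM per gene and library, per the file headers. The authors' counts are whole numbers in every intact row and were used without rounding; they were recorded under the looser unit of expected counts only because 1 broken line in the deposited table holds shifted cells. The table has 23378 lines below its header, and 2 were left out: that line and the row before it, which has no values. The deposited FPKM is 0 exactly where the count is 0. The ratio of FPKM to count, between the libraries, was 1.31, the same as the ratio of the summed counts, so the authors' FPKM scales each library by its total count. Across 11714 genes with 50 counts or more in each library, the deposited FPKM had a median of 0.648 of the value computed from the exonic length of GENCODE 29 and the summed counts, so its length or its total follows another definition. A ratio between libraries does not depend on this, while the thresholds of 1 and 5 FPKM do.

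Symbols were taken from the table. In 23 rows the symbol had been turned into a date, and it was replaced by the reference symbol of the gene ID. Of the 23376 IDs, 23165 matched GENCODE 29 on GRCh38, which gave positions, gene types and transcript sequences. Rows that share a symbol were summed, which concerned 31 symbols and left 23321 genes. The summed counts were 13482913 for the control and 10289206 for the GGT7 library. A count of 0 allows up to 3 counts, or 0.223 and 0.292 CPM for the control and GGT7 libraries. The 10 genes with most counts held 8.22% of the control and 8.38% of the GGT7 counts.

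The difference of a gene is log2((GGT7 FPKM + 1)/(control FPKM + 1)), which understates the change of low genes; folds in the text are ratios of FPKM without the pseudocount. Genes with at least 1 FPKM in the higher library were counted as measured, and 2-fold or more was the rule of size. Intervals are exact conditional (Clopper-Pearson) 95% intervals of the ratio of counts, given the totals. They cover counting error only, since reads without molecular identifiers are not independent molecules. No test of groups was run. The number of 2-fold genes from counting error was taken from 100 simulated pairs of libraries without a difference.

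Before the data were examined, 44 gene lists were fixed, and GGT7 was left out of them. The median of each list with at least 5 measured members was placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean level, as a description of these 2 libraries. A list stands apart below the 2.5th or above the 97.5th percentile. A further 7 lists were chosen after seeing the data and are used in the closing section only.

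The genes named in the text follow a rule also fixed before the data were examined. It takes GGT7 and the 12 largest differences each way among genes above 0 in both libraries and at 5 FPKM or more in the higher. It leaves out small RNAs, RNAs with antisense names, features with clone names (some of them typed as protein-coding) and sex-specific genes. It adds 3 members of each list that stands apart in the direction of the list and 1 in the other, the largest member each way of other lists, genes at 0 in one library only, and genes of GGT7's family, RAB7, mitophagy and proliferation by name. Some of the genes it takes are not reported here.

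The alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter or 5 FPKM in the higher library, rescaling by the median ratio or the upper quartile, TMM scaling with edgeR 4.0.16, size factors with DESeq2 1.42.0, a 1.5-fold rule, rows as deposited, and random lists not matched on level. Protein-coding genes alone, a minimum of 50 counts over both libraries, removal of the trend with GC content and length by lowess (span 0.3), the TMM and DESeq2 scalings for lists, and lists without members of the ATF4 list were chosen after seeing the data. Copies of a gene were sought with BLAST 2.17.0 among the longest transcripts of all genes, at 95% identity over 30% of the transcript, and overlapping genes by 100 shared exonic bases or more on either strand. Of the 128 genes the naming rule took, 19 had such a copy and 46 an overlapping gene, and their values are uncertain as far as reads were shared. Not each of them is marked where it is named below. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9 and R 4.3.3.

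The calculations were tested on simulated data of these 2 library sizes. All 50 genes set 4-fold higher were called, 72.0% of 50 set 4-fold lower (0.25 of the control), and 16.0% and 4.00% of the 50 set 2-fold higher and lower, which the pseudocount pulls below the rule of size. Of 13041 genes left alone, 0.268% were called, and the interval held the true ratio for 95.5%. All 10 lists of 30 members set 1.5-fold higher lay above the 97.5th percentile. Of 200 lists without a change, 1.00% lay above it and 3.50% below the 2.5th.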

Results

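RNA sequencing was carried out on AGS cells, an established human gastric adenocarcinoma line, that had been stably transfected with a control plasmid or with a plasmid for GGT7, a member of the gamma-glutamyltransferase family. Each group held 1 library, taken at 2 weeks. The deposited table gave 13482913 counts for the control library and 10289206 for the GGT7 library, over 23376 intact gene rows. At this depth 1 FPKM, a fragment count scaled by gene length and library total, stood for about 112 counts of the median gene in the control library and 85.1 in the GGT7 library. With 1 library per group the differences below have no replicate check, and no p-value was computed. The intervals are exact 95% intervals of a ratio of counts, and they cover counting error only.

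The series asks what a higher level of GGT7 does in gastric cancer cells, with RAB7 and mitophagy, the removal of mitochondria by autophagy, in its title. GGT7 (ENSG00000131067, GRCh38 chromosome 20, 34844720 to 34872860, minus strand) had 90 counts in the control library and 470 in the GGT7 library. Its level was 1.78 FPKM in the control and 12.2 FPKM in the GGT7 library, 6.84-fold higher (5.45 to 8.67). The counts do not separate transcripts of the plasmid from those of the chromosomal gene. The log2 difference of (FPKM + 1) was 2.25, rank 10 among the protein-coding genes that were above 0 in both libraries and at 5 FPKM or more in the higher. GGT1, the best known enzyme of the family, was at 2.84 FPKM in the control and 2.75 in the GGT7 library, a difference within its counting interval. GGT1 shares sequence with several copies in the family, so its value is uncertain where the counting split reads between them. GGT2 had 3 and 1 counts, and GGTLC1 had 13 and 17.

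Most genes differed little between the libraries. Of 14215 genes with at least 1 FPKM in the higher library, 12955 (91.1%) lay within 1.5-fold on the log2(FPKM + 1) scale, and the median log2 difference was -0.03. By the rule of size, 122 genes were 2-fold or more higher in the GGT7 library and 165 were 2-fold or more lower. Counting error alone, simulated without any difference, gave on average 35 higher and 39.9 lower genes. The counting interval of the ratio lay above 1 for 117 of the 122 and below 1 for 143 of the 165. These genes were picked by the same counts, so the intervals are no separate check of them. Among protein-coding genes 72 were higher and 77 lower. Folds of named genes are ratios of FPKM, while members past 1.5-fold or 2-fold, medians and directions are counted on the log2(FPKM + 1) scale. The counts depend on the rule: with a pseudocount of 5 there were 29 and 24 genes, and with 0.1 there were 349 and 486.

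**Figure D1:**
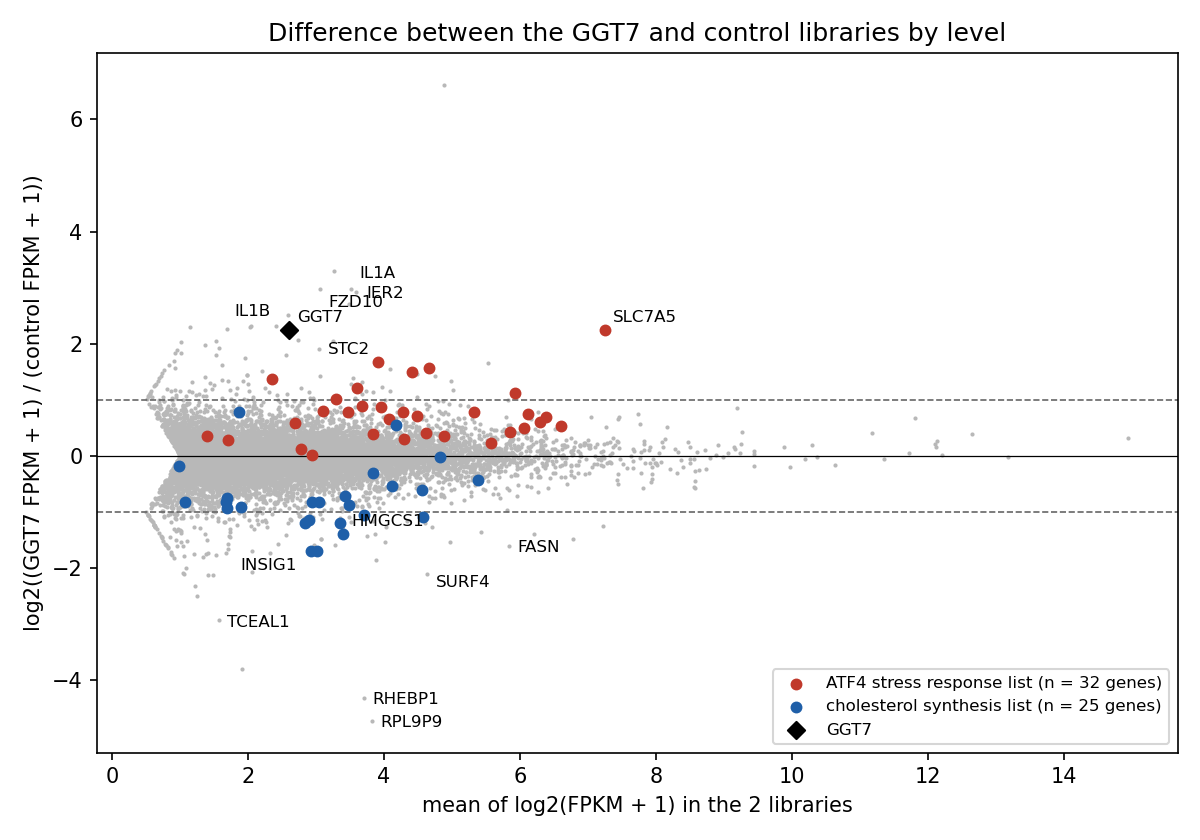
Log2 difference between the GGT7 and control libraries (vertical axis, FPKM + 1) against the mean log2 level of both libraries (horizontal axis), 1 point per gene with at least 1 FPKM in the higher library; dashed lines mark 2-fold. GGT7 (diamond) lies at 2.25, all 32 genes of the ATF4 list (red) lie above 0 and the cholesterol list (blue) lies mostly below 0.

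At 5 FPKM or more in the higher library, and with small RNAs and clone-named features left out, the 12 genes most above the control were GGT7 and the 11 named here, among them IL1A, IL1B, FZD10, IER2 and SLC7A5. IL1A and IL1B, neighbouring genes on chromosome 2 for the cytokines interleukin-1 alpha and beta, were 10.2-fold (8.14 to 12.8) and 7.82-fold (6.31 to 9.79) higher. FZD10, a receptor for WNT ligands, had 174 counts in the control and 1516 in the GGT7 library, 11.4-fold higher (9.75 to 13.4). The immediate early gene IER2 was 9.60-fold higher (8.47 to 10.9), with the limit that its exons overlap an antisense gene and the strand setting of the counting is not given in the sources used here. SLC7A5, the large neutral amino acid transporter, combined a high level with a large difference, 68.8 FPKM in the control and 329 in the GGT7 library, 4.79-fold higher (4.64 to 4.94). The histone gene HIST1H4H was 8.14-fold higher (6.90 to 9.66), and the zinc finger genes RBAK and ZNF33B were 9.61-fold (7.97 to 11.7) and 12.8-fold (9.78 to 16.96) higher. RBAK and SLC7A5 each overlap another annotated gene over part of their exons. The remaining features among the 12 were RPL17-C18orf32 (14.1-fold, 10.8 to 18.8), TUBBP1 (8.79-fold, 6.70 to 11.7) and ERCC6-PGBD3 (5.63-fold, 4.56 to 7.02). These are 2 read-through genes and a tubulin pseudogene, whose reads can be shared with the parent genes, so their values are uncertain.

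By the same rule, the 12 genes most below the control included INSIG1, MSMO1, FASN and SURF4. INSIG1, which holds the sterol sensor in the endoplasmic reticulum, was 3.95-fold lower (3.46 to 4.52), and MSMO1, an enzyme of cholesterol synthesis, was 3.89-fold lower (3.29 to 4.61). FASN, fatty acid synthase, was at 99.4 FPKM in the control and 31.9 in the GGT7 library, 3.12-fold lower (3.02 to 3.23). SURF4, a cargo receptor of the secretory pathway, had 5281 counts in the control and 874 in the GGT7 library, 4.61-fold lower (4.29 to 4.96). TCEAL1 had 263 counts in the control and 2 in the GGT7 library, a ratio of 100.4 with an interval from 27.5 to 833. ADNP, a chromatin-associated homeobox protein, was 3.46-fold lower (3.21 to 3.73), DDAH1, which degrades dimethylarginine, was 3.89-fold lower (3.42 to 4.45), and FAM109B was 7.22-fold lower (4.95 to 10.9). ADNP, DDAH1 and TCEAL1 each overlap another annotated gene over part of their exons. The other features among the 12 were the pseudogenes RPL9P9 (40.9-fold, 26.9 to 65.5), RHEBP1 (29.6-fold, 16.4 to 59.8) and ARMCX7P (4.61-fold, 2.92 to 7.61) and the read-through gene STX16-NPEPL1 (4.97-fold, 3.73 to 6.75), with the same uncertainty. No gene outside clone names was at 0 in one library and at 5 FPKM or more in the other.

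At the level of RNA, most genes of the pathways in the title of the series differed little. RNA levels do not show protein amounts, the activity of RAB7 or mitophagy itself, which were not measured here. RAB7A (ENSG00000075785, GRCh38 chromosome 3, 128726122 to 128814796, plus strand), the small GTPase of late endosomes, was at 31.9 FPKM in the control and 31.5 in the GGT7 library, a fold of 0.985 with an interval from 0.925 to 1.05. Of 42 measured genes of mitophagy, 41 lay within 1.5-fold, and the median log2 difference of 0.04 was at percentile 90.5 among 10000 random lists matched on level. The members farthest apart were CALCOCO2, an autophagy receptor, 1.43-fold higher (1.31 to 1.55), and TBC1D17, a RAB GTPase activating protein, 1.73-fold lower (1.46 to 2.05). PINK1, the kinase that marks damaged mitochondria, was 1.37-fold lower (1.26 to 1.499), with the limit that it shares exonic sequence with its antisense gene. The mitophagy receptors BNIP3 and BNIP3L were at 1.06-fold (0.92 to 1.22) and 1.19-fold (1.05 to 1.36) of the control.

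In the list of core autophagy genes 42 of 45 lay within 1.5-fold, with a median of 0.02 at percentile 88.5. Its largest values were TFE3, a transcription factor for lysosomal and autophagy genes, 2.89-fold higher (2.62 to 3.19), and ATG5, needed to extend the autophagosome, 2.02-fold lower (1.73 to 2.35). MAP1LC3B, which encodes the autophagosome protein LC3B, was 1.56-fold higher (1.46 to 1.68), while the receptor SQSTM1 was 1.17-fold lower (1.12 to 1.23); SQSTM1 overlaps a neighbouring gene. All 43 measured RAB7 regulators, effectors and tethering genes lay within 1.5-fold, from TBC1D2 at 1.49-fold higher to VPS18 at 1.47-fold lower, and their median of -0.02 was at percentile 53.8. Lysosomal genes stood slightly higher: 37 of 63 were above 0 (38 under some scalings), the median was 0.08, and its percentile was 99.6. PPT1, ATP6V1G1 and CTSB led them at 1.61-fold, 1.51-fold and 1.56-fold, while ATP6V0B was 1.47-fold lower and the lysosomal membrane gene LAMP1 1.26-fold lower (1.19 to 1.34). PPT1 and ATP6V0B overlap another annotated gene.

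Mitochondrial gene groups stayed within the range of random lists. The 78 nuclear-encoded genes of oxidative phosphorylation had a median log2 difference of 0.00 (percentile 74.7), with NDUFB8 1.78-fold higher and COX7A2L 1.90-fold lower at the ends. NDUFB8 shares sequence with the overlapping gene AL133352.1, so its value is uncertain. The 71 mitochondrial ribosomal protein genes had a median of 0.03 (95.1), from MRPL17 at 1.77-fold higher to MRPL27 at 1.60-fold lower. The 26 genes of mitochondrial biogenesis and dynamics had a median of -0.03 (47.6), and the 23 genes of the tricarboxylic acid cycle 0.06 (88.0). Of 13 listed mRNAs of the mitochondrial genome, only 6 were in the deposited table. All 6 were measured, with a median of 0.13 (85.1). The central 95% of random medians was wide for so few genes, from -0.22 to 0.25. Genes of the mitochondrial genome held 2.79% of the control and 3.15% of the GGT7 counts. MT-ND5 was 1.60-fold higher (1.58 to 1.61) and MT-ND6 1.18-fold lower (1.12 to 1.25).

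Target genes of ATF4, the transcription factor of the integrated stress response, were higher in the GGT7 library as a group. All 32 measured members had a log2 difference above 0, 20 were 1.5-fold or more higher and 8 were 2-fold or more higher. The counting interval lay above 1 for 30 of the 32. The median log2 difference was 0.70, above all 10000 matched random lists, whose medians lay mostly between -0.11 and 0.10. After SLC7A5, the largest differences were in STC2, a secreted glycoprotein, 3.47-fold higher (3.18 to 3.79), and SLC7A11, the cystine transporter, 3.10-fold higher (2.93 to 3.27). SLC7A11 overlaps an antisense gene over part of its exons. The growth factor gene GDF15, named here from the list of p53 targets, was 2.99-fold higher (2.70 to 3.32). Genes of the unfolded protein response of the endoplasmic reticulum, in contrast, had a median of -0.02 at percentile 43.6, and all 26 lay within 1.5-fold, from ATF6 at 1.25-fold higher to DERL2 at 1.61-fold lower in FPKM.

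Genes of cholesterol synthesis and other targets of the sterol-regulated transcription factor SREBP2 were lower in the GGT7 library as a group. Of 25 measured members 23 had a log2 difference below 0, 18 were 1.5-fold or more lower and 8 were 2-fold or more lower. The counting interval lay below 1 for 22. A member close to 0, PMVK, moves to the other side under DESeq2 size factors, which leaves 22 below 0. The median was -0.83, below all 10000 matched random lists. Besides INSIG1 and MSMO1, HMGCS1, which makes the precursor of mevalonate, was 2.92-fold lower (2.62 to 3.28). HMGCS1 overlaps another annotated gene over part of its exons. SC5D, a late enzyme of the pathway, went the other way at 2.13-fold higher (1.82 to 2.49). The list of fatty acid synthesis and oxidation genes had a median of -0.01 (percentile 55.3) over 28 members, with 4 of them 1.5-fold or more lower, FASN at one end and the carnitine carrier gene SLC25A20 at the other, 1.31-fold higher (1.12 to 1.54).

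**Figure D2:**
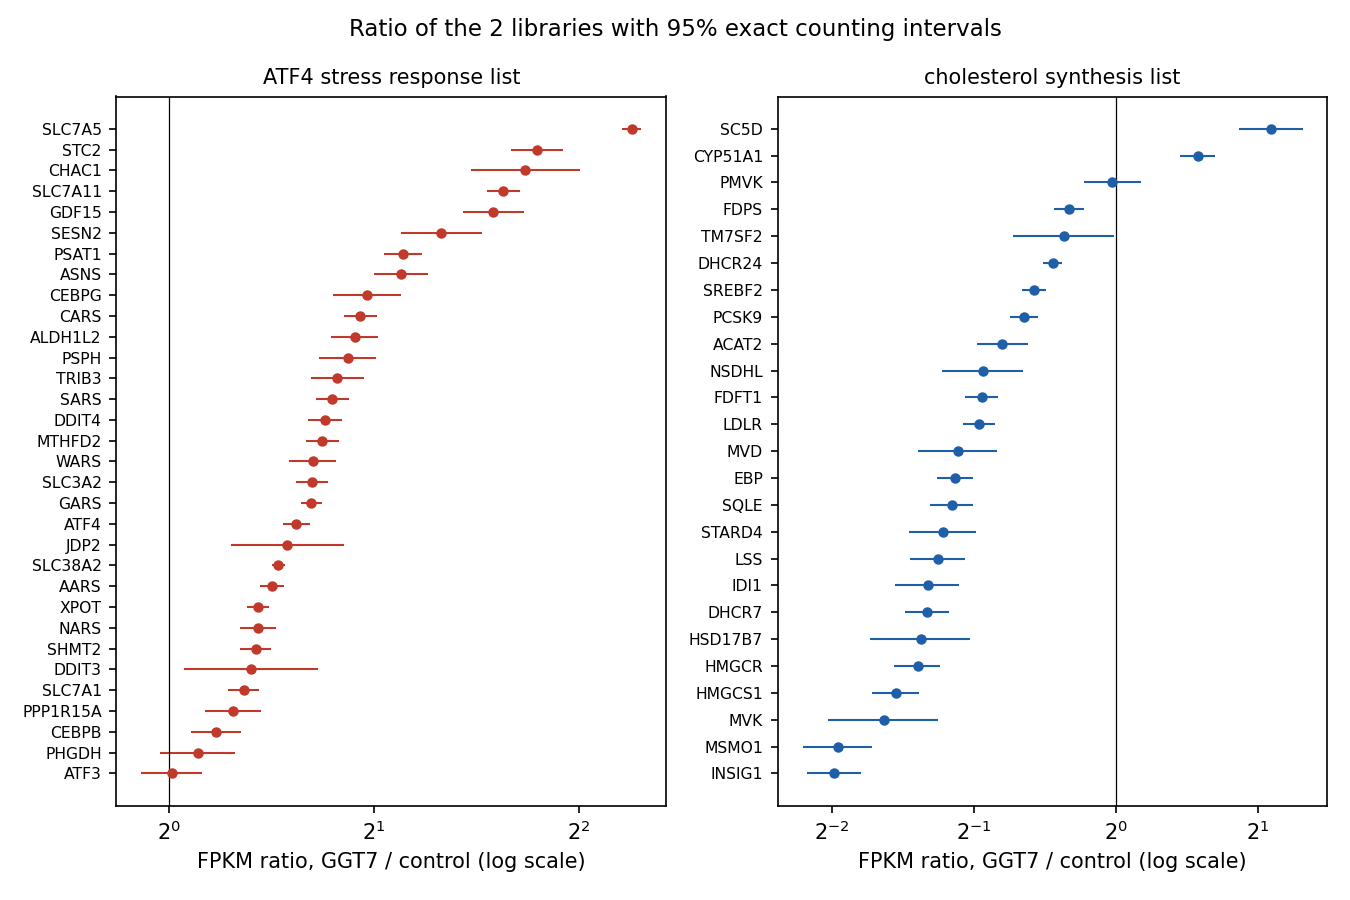
FPKM ratio of the GGT7 library to the control library on a log axis for each measured member of the ATF4 list (left, 32 genes) and the cholesterol list (right, 25 genes); bars are exact 95% intervals of the ratio and cover counting error only. SLC7A5 at 4.79 leads the ATF4 list, and INSIG1 is lowest in the cholesterol list, at 0.25.

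Further stress groups also stood apart. Heat shock and chaperone genes were lower: 15 of 16 were below 0, the counting interval lay below 1 for 14, and the median of -0.47 was below all 10000 matched lists. HSPA1B, an inducible chaperone that shares sequence with other loci, was 3.02-fold lower (2.72 to 3.36), HSPA8, the constitutive chaperone, 2.63-fold lower (2.54 to 2.73), and HSPH1 1.85-fold lower (1.73 to 1.98). HSF1, the regulator of the heat shock genes, was 1.31-fold higher (1.19 to 1.45). Targets of the antioxidant regulator NRF2 were higher, with a median of 0.26 at percentile 99.99 and 20 of 27 members above 0 (21 under some scalings). SLC7A11 belongs to this list as well, together with ABCC2, an export pump, 3.50-fold higher (2.53 to 4.91), and the thioredoxin gene TXN, 1.63-fold higher (1.53 to 1.73). ME1 was 1.38-fold lower (1.20 to 1.58). The list of glutathione and gamma-glutamyl cycle genes had a median of 0.10 at percentile 98.7, with 19 of 33 above 0 (20 under some scalings). Its largest members were SLC7A11, CHAC1, a glutathione-degrading enzyme, 3.33-fold higher (2.78 to 4.01), and MGST1, 1.95-fold higher (1.75 to 2.17). GSTM1, which overlaps GSTM2, was 1.27-fold lower (1.10 to 1.45). Without the 3 members that the ATF4 list also holds, the median was 0.05 at percentile 91.5, within the range of random lists. With these members kept, the list also came within the range without a filter on low values (0.0694, 96.8) and with protein-coding genes alone (0.0694, 95.94). Other antioxidant enzymes had a median of -0.10 (percentile 9.33; at the limit of 5 FPKM 0.0326, 66.9), with MSRB2 1.62-fold higher and GLRX 1.58-fold lower. Hypoxia targets had 0.07 (91.9), with DDIT4 1.69-fold higher and PFKFB4 2.04-fold lower, and glycolysis genes -0.04 (26.1), with the glucose transporter genes SLC2A1 1.17-fold higher and SLC2A3 2.00-fold lower.

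Groups tied to growth signals went in both directions. Immediate early genes had a median of -0.29, below all 10000 matched lists, with 17 of 22 below 0. MYC was 2.55-fold lower (2.36 to 2.75), JUND 2.39-fold lower (2.12 to 2.70) and NR4A1 1.73-fold lower (1.66 to 1.80), while IER2, described above, was the member farthest the other way. Output genes of the MAPK pathway had a median of 0.23 (percentile 99.96), with DUSP4 1.65-fold higher (1.54 to 1.77), SPRY4 1.75-fold (1.45 to 2.12) and ETV5 1.39-fold (1.27 to 1.52), and with MYC as the member farthest the other way. YAP/TAZ targets had a median of 0.26, above all 10000 lists. NT5E was 2.28-fold higher (1.91 to 2.74), AMOTL1 1.70-fold (1.55 to 1.87) and IGFBP3 1.52-fold (1.41 to 1.63), while CYR61 was 1.66-fold lower (1.56 to 1.77). Mitotic genes were slightly lower, with a median of -0.12 at percentile 0.38 and 34 of 46 below 0 (at least 32 under every scaling). Among random lists not matched on level the same median was at percentile 3.40, within the range. KIF20A was 1.73-fold lower (1.57 to 1.90), CDC25C 1.45-fold lower and CCNB1 1.305-fold lower, and NDC80 was 1.23-fold higher. The proliferation marker MKI67 was 1.26-fold lower (1.21 to 1.31). Genes of the G1/S phase had a median of -0.03 (percentile 32.7), with GINS4 1.53-fold lower at its lower end. CCND1, cyclin D1, was at 38.2 and 40.7 FPKM, and the cell cycle inhibitor gene CDKN1A at 20.5 and 20.7.

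The remaining lists lay within the range of matched random lists at the limit of 1 FPKM, and some depended on the settings. Targets of p53 had a median of 0.01 (percentile 75.6), apoptosis regulators -0.08 (17.1; at the limit of 5 FPKM 0.0468, 85.2), targets of TNF and NF-kappaB -0.13 (8.85; at 5 FPKM 0.00289, 62.8), the type I interferon response 0.07 (94.3), antigen presentation genes 0.11 (95.3), and regulators of PI3K, AKT, FOXO and mTORC1 -0.06 (26.9). WNT targets, with 6 measured members, had -0.04 (43.8), genes of nucleolar and ribosome biogenesis -0.09 (7.52), cytosolic ribosomal proteins 0.04 (89.9; 98.03, outside the range, among lists not matched on level), proteasome subunits -0.04 (31.2) and replication-dependent histones -0.07 (13.02). Epithelial adhesion and keratin genes had 0.09 (94.9), with CLDN1 1.95-fold higher and KRT8 1.54-fold lower, and mesenchymal genes 0.08 (91.4), with SNAI2 1.66-fold higher and FN1 3.27-fold lower. The mesenchymal list lay above the range at the limit of 5 FPKM (0.291, 99.97) and after removal of the GC and length trend (0.153, 97.89), the latter chosen after seeing the data. Housekeeping genes had -0.05 (14.3; at 5 FPKM -0.111, 1.14, below the range), with YWHAZ 1.52-fold higher and TUBA1B 2.65-fold lower; TUBA1B shares sequence with TUBA1C. In all, 6 of 38 placed lists lay above the central 95% of their matched random lists and 4 below it. Independent draws of genes would give 1.9 in all. Some lists share members, such as MYC and SLC7A11, and genes regulated together can differ together between cultures. The number outside by chance is therefore not known.

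**Figure D3:**
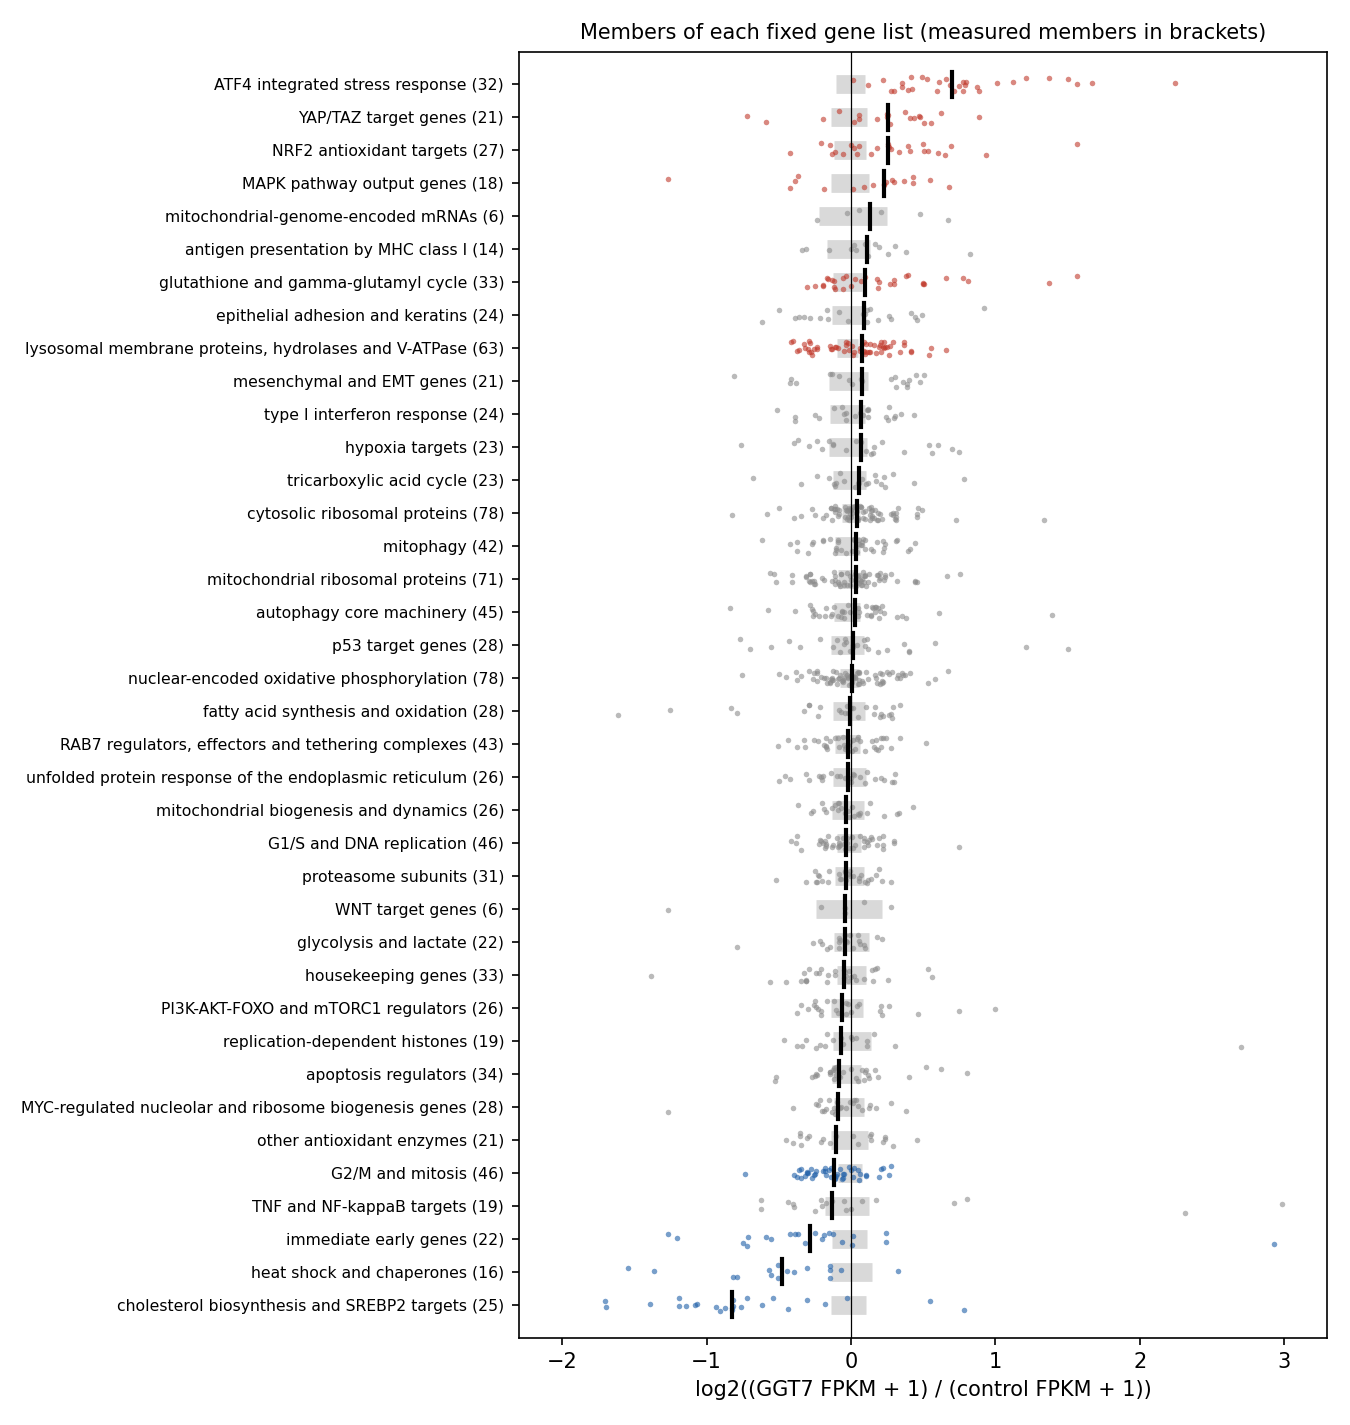
Log2 difference between the GGT7 and control libraries for each measured member (points) of the 38 placed gene lists, with the median as a black bar and the central 95% of medians of 10000 matched random lists as a grey band; red marks lists above the band and blue lists below it. The ATF4 list has the highest median, at 0.70, and the cholesterol list the lowest, at -0.83.

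Markers of cell types other than epithelial cells, and of the gastric and intestinal epithelium itself, were mostly too low to place. Fewer than 5 members were measured in the lists of leukocyte, endothelial, erythroid, fibroblast and gastrointestinal markers and of metallothioneins. Of 38 listed gastric and intestinal epithelial markers, 16 were in the deposited table and 3 were measured. The 1 measured leukocyte marker was CD68, a lysosomal glycoprotein, at 1.11 FPKM in the control and 6.08 in the GGT7 library, 5.49-fold higher (4.21 to 7.23); its exons overlap those of another annotated gene. ESAM was 2.08-fold higher and CDH5 1.16-fold lower among 3 endothelial markers, and COL1A1 was 1.54-fold lower among 3 fibroblast markers. The erythroid gene HBE1 was at 2.52 and 3.97 FPKM, the gastrointestinal factors GATA5 and GATA6 differed within their counting intervals, and MT2A was 1.31-fold higher.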

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

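No test stands behind these results, so they were compared by size; the protein-coding, 50-count, GC, TMM and DESeq2 list settings and the lists without ATF4 members were chosen after seeing the data. The counts of 2-fold genes depend on how low genes are treated. Against 122 higher and 165 lower genes, a pseudocount of 0.1 gave 349 and 486, a pseudocount of 5 gave 29 and 24, a level of 5 FPKM gave 60 and 64, the 1.5-fold rule gave 554 and 706, and protein-coding genes alone gave 72 and 77; a minimum of 50 counts gave 95 lower genes. Fewer genes enter under the limits of 5 FPKM, protein-coding genes and 50 counts. Under the scalings, without a filter and with rows as deposited, the counts stayed within 1.5 times. GGT7's log2 difference of 2.25 was 2.71 with a pseudocount of 0.1 and 1.34 with 5, by the construction of the measure. Of the 10 lists that stood apart, 8 did so under all alternatives run. Mitotic genes, with an unmoved median of -0.12, were at percentile 3.40 among lists not matched on level. The glutathione list lost its place without a filter (median 0.0694, percentile 96.8), among protein-coding genes (0.0694, 95.94) and without ATF4 members (0.0492, 91.5). Lists within the range left it in 4 cases: ribosomal proteins unmatched (0.0435, 98.03), housekeeping genes at 5 FPKM (-0.11, 1.14), and mesenchymal genes at 5 FPKM (0.29, 99.97) and after removal of the GC and length trend (0.153, 97.89). The cause was not tested. The log2 difference of single named genes moved by more than 0.5 of the log2 width of their counting interval in 95 of 508 comparisons, and none changed sign from a 2-fold difference.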

Other observations

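Of the tests below, those on shared reads, on the trend with GC content and length, on the balance of counts between copies, on the unfolded protein response and on fatty acid oxidation were chosen only after the results they bear on had been seen, as were the 7 gene lists described here and the step of leaving out ATF4 members from them. Of 20 cytosolic aminoacyl-tRNA synthetases 17 were above 0, with a median log2 difference of 0.28 at percentile 99.99 of matched random lists and CARS highest at 0.87, and 17 mitochondrial ones had a median of -0.04 at percentile 41.4; the difference between these lists was not tested. Without the 6 cytosolic genes that the ATF4 list also holds, the median of the other 14 was 0.14 at percentile 95.97, within the range of random lists. Amino acid transporters (18 genes, median 0.36, above all 10000 random lists) and enzymes of serine and one-carbon metabolism (11 genes, median 0.32, percentile 99.96, PSAT1 at 1.12) were higher too, but they also came within the range once their 5 and 6 members of the ATF4 list were left out (medians 0.07 and -0.03, percentiles 86.1 and 51.7). Lipid genes went apart. Of 11 genes of fatty acid synthesis and desaturation 10 were below 0, with a median of -0.29 at percentile 0.15. Of 17 fatty acid oxidation genes 13 were above 0 (12 to 14 over the scalings), with a median of 0.16 at percentile 99.2. By size and direction these lists appear to split the fixed list of fatty acid synthesis and oxidation genes. That list of 28 genes had a median of -0.01 at percentile 55.3, and the difference between its parts was not tested. All 8 measured alpha- and beta-tubulin genes were below 0, from TUBB6 at -0.01, which moves above 0 under 3 of the 4 rescalings, to TUBA1B at -1.39 (-1.37 under median rescaling), with a median of -0.29 at percentile 0.38. Tubulin genes share sequence, so these values are uncertain where the counting split reads between them. Medians of protein-coding genes per chromosome ran from -0.08 on chromosome 19 to 0.07 on chromosome 18.

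The higher level of ATF4 targets was set against 2 explanations. A wrong library scale had no test that could have come out another way: the list was picked for its place among the random lists, scaling by total count holds these near 0, and the 4 rescalings moved log2 values by only -0.01 to 0.03. After removal of the trend with GC content and length, which moved genes by a median of 0.03 and up to 0.27, the list median was 0.72, with values for all 32 members. Stress of the endoplasmic reticulum as the trigger was looked for in the unfolded protein response list. That list had a median of -0.0212 and its highest member stood at 0.31. It shares 0 members with the ATF4 list, so it cannot decide on a stress of the endoplasmic reticulum that acts through ATF4 alone. The values argue only against a broad rise of the other targets of that response. A response to the GGT7 plasmid stays open as a hypothesis, and with 1 library per group so does any difference in culture or preparation between the 2 libraries, which was not tested.

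The lower level of cholesterol genes was treated in the same way. A wrong library scale was not tested here either, for the same reasons. After removal of the GC and length trend the list median was -0.82, with values for all 25 members. A lower level of lipid enzymes of every kind was not seen: the fatty acid oxidation genes had a median of 0.16 and no member below -0.09. These genes were set apart only after the fixed list of fatty acid synthesis and oxidation, with a median of -0.01, had been seen. Their median is therefore a description and no separate test. The medium and the sterol supply of the 2 cultures were not tested, and the plasmid stays open as a hypothesis here too.

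Many of the features with the largest differences share sequence with another locus. Of 31 features 4-fold or more apart, 28 could be searched, and 13 (46.4%, exact 95% interval 27.5 to 66.1) had a copy at 95% identity or more, against 93 of 496 random measured genes (18.8%, 15.4 to 22.5). Among protein-coding genes alone the shares were 33.3% (14.6 to 57.0) and 10.5% (7.53 to 14.2). With overlapping genes counted as well they were 64.3% (44.1 to 81.4) and 49.2% (44.7 to 53.7), intervals that overlap. The most extreme, chosen here after its values were seen, was RP11-371A22.1, a processed pseudogene 99.2% identical to EEF1G, with 35 counts in the control and 3939 in the GGT7 library, while EEF1G was at 52.3 and 54.2 FPKM. At the depth of the control the feature was higher by 5127 counts and its 3 partners together differed by -322. Counting error alone gave a mean of 0.77 such features and at most 3 in 100 draws, so it does not account for the 31. If reads moved between loci, the partners, copies and overlapping genes summed, would go the other way. They did in 11 of 17 features with a partner in the table (64.7%, interval 38.3 to 85.8). In 3 of the 17 they did so by at least 0.5 of the feature's own change. Such a sum can go the other way although the closest copy does not, as with EEF1G. Some partners had few counts, such as 3 in the control and 8 in the GGT7 library for TCEAL1. Reads that were not counted at any locus are not in these sums, so a shift of reads between copies or overlapping loci cannot be told apart from real differences of these features. Among the 4-fold genes named in the sections above, GGT7, FZD10, IL1A, IL1B, HIST1H4H, ZNF33B, SURF4 and FAM109B had neither a copy nor an overlapping gene by these limits.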
